A study of Mus musculus with 9 samples.

How the data were processed

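The data were 9 deposited StringTie tables of mouse cortex, which hold for each transcript a mean read coverage per base, an FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) and a TPM (length-normalized transcript share, scaled to a fixed total), as named by the deposited attributes. TPM was the unit of the main tests, FPKM was an alternative unit, and the deposited coverage served only to estimate read numbers. Read counts are not used here, so no count-based test was run. Per the submitters' processing notes, reads were aligned with HISAT2 2.0 and quantified with StringTie 1.3 against GRCm38/mm10. Per the file headers the StringTie version was 1.3.4d, run with the options -e and -B on a merged annotation and without a strand option, so the values of genes that overlap on opposite strands are uncertain.

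Per the labels, each group held 3 libraries from cohorts of mice with 1 h of middle cerebral artery occlusion and 6 h of reperfusion, or with sham surgery. Per the submitters' notes, total RNA of the control oligo and knockdown groups was isolated with mirVana and treated with DNase I, and libraries were made with the TruSeq stranded poly(A) mRNA kit and sequenced as pairs on a NovaSeq. Library details of the sham samples, from an earlier data set of the same laboratory, are not given in the sources used here. All p-values reflect the variation between these 3 samples per group.

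The tables held 131100 transcripts of 52550 genes in each library. TPM and FPKM were summed over the transcripts of each gene ID. Of the gene IDs, 52403 (99.72%) were found in GENCODE M21, and 95.17% of those had the same start and end there. Gene types came from GENCODE M21, which gave 17046 of the 17080 genes kept a type. A symbol was shared by more than 1 gene ID in 90 cases, which were kept as separate genes. The length of a read pair was taken as the most frequent number of aligned bases (coverage times length) of single-exon transcripts that hold few reads. Aligned bases came from the ratio of the deposited coverage to FPKM, and aligned pairs are these bases divided by the length of a pair.

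Aligned bases assigned to transcripts were 89.0 to 90.7% of the total. A gene was kept if its TPM was at least 1 in at least 3 of the 9 libraries, which left 17080 genes. Each comparison was fitted on its own 6 libraries with limma 3.58.1 (limma-trend, R 4.3.3) on log2(TPM + 1), with no further scaling and no covariate, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were control oligo MCAO against sham, knockdown against control oligo, and knockdown against sham. Gene lists were tested with camera of the same package at the preset inter-gene correlation of 0.01, for lists with at least 5 genes kept and adjusted over the lists tested, and with a correlation estimated from the residuals. Members were also adjusted over the list alone. The scaled values come from median-ratio scaling, in which each library was divided by its median ratio to the geometric mean library. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for parsing and plots.

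The 41 gene lists were written before the data were examined and held 738 genes, of which 687 were kept. They were immediate early genes, heat shock chaperones, unfolded protein response, cytokines and chemokines, NF-kB target and feedback genes, interferon-stimulated genes, pro-apoptotic genes, anti-apoptotic genes, p53 target genes, hypoxia-induced genes, oxidative stress response, pan-reactive astrocyte genes, extracellular proteolysis, blood-brain barrier, glucocorticoid-induced genes, glutamate receptors, GABA receptors, presynaptic and vesicle genes, potassium channels, neurotrophic factors and neuropeptides, cholesterol biosynthesis, cytosolic ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded genes, replication-dependent histones and short structural noncoding RNAs. The other 15 were markers of excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial cells, pericytes and smooth muscle, neutrophils, monocytes and macrophages, lymphocytes, choroid plexus and ependyma, striatum, meninges and fibroblasts and erythroid cells. The lymphocyte list kept too few genes to be tested.

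Genes were named by a rule fixed before the data were examined. In each comparison the 10 largest positive and the 10 largest negative log2 changes were named among genes past the threshold whose groups did not overlap, leaving out clone-type symbols, pseudogenes and mitochondrial genes. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named and said not to pass. Up to 4 members of each list with the smallest p were added. AY036118 was kept under the rule although its symbol is a sequence accession. mt-Ts2 and Gm7808 lie outside the rule and were named after their values were seen, as were Saa3, mt-Th and mt-Tl2. Some genes that the rule covers, and a test on 1 further gene, are not reported here. Il1b, a member of a fixed list, was named to describe 1 library. Transcripts shorter than a read pair, and mitochondrial genes with nuclear copies, have uncertain values.

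The effect of the knockdown over the genes changed in MCAO was measured as the median of their knockdown minus control oligo log2 changes, and by a covariance. As the control oligo libraries enter both sides, values were compared with 1000 simulated knockdown groups without an effect, built from the deviations of whole libraries from their group means, drawn with replacement and with random sign. The overlap of the comparisons with sham was compared in the same way with 100 simulated pairs of groups.

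Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, FPKM, median-ratio scaling, quantile normalization, 1 fit of all 9 libraries, voom weights on estimated read pairs, the replicate number as a block, an absolute log2 change of at least 1, an estimated correlation for camera, and leaving out each library. TPM recomputed over nuclear protein-coding genes, a leukocyte marker covariate (mean of the neutrophil and monocyte lists) and fry, a limma test of each list by itself, were added after the data were seen, as was the estimated correlation on scaled or recomputed values and with a library left out. Each regrouping of the 6 libraries of a comparison into 3 and 3 was also fitted.

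The test was tested on simulated data, drawn from the means and spreads of the real genes with 100 genes moved by each of 2 sizes of log2 change. At the control oligo against sham comparison 55% of changes of 1 and 89% of changes of 2 were recovered, with 7 false calls among the unchanged genes. The knockdown against control oligo comparison recovered 19% and 76% with 1 false call, and knockdown against sham 51% and 86% with 3. Of 20 unmoved lists camera called 0 in each comparison, but these simulated genes were drawn independently, and on the regrouped real libraries camera at the preset correlation passed 5 to 28 of the 40 lists tested.

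Isoforms, splicing, unannotated transcripts and the enhancer RNA itself are not analysed here.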

Results

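RNA of the cerebral cortex of male C57BL/6N mice, 9 to 12 weeks old, was sequenced in 3 groups of 3 libraries each. MCAO is the occlusion of the middle cerebral artery with a filament, a model of ischemic stroke, and here it lasted 1 h and was followed by 6 h of reperfusion. Before MCAO the mice received, through the lateral ventricles, a locked nucleic acid antisense oligonucleotide either against the enhancer RNA eRNA_06347 (knockdown, replicates 2, 3 and 4) or with a negative control sequence (control oligo, replicates 1, 2 and 3). The tissue was the infarcted ipsilateral cortex. Sham mice had the neck incision without a filament, and their libraries (replicates 1, 2 and 3) came from an earlier data set of the same laboratory. The sham libraries held 29.2 to 31.2 M aligned read pairs of 51 nt reads, and the 6 MCAO libraries 17.5 to 19.6 M pairs of 141 nt reads, as computed from coverage (M, mega). Between 14992 and 16571 genes per library reached a TPM (transcript share scaled to a fixed total) of 1. Values are the mean TPM ± SD of the 3 libraries of a group unless said otherwise, and log2 changes are differences of log2(TPM + 1), which understates the folds of genes of low TPM.

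The classes of RNA in the libraries differed between the data sets. Small structural RNAs, such as the 7SL RNA of the signal recognition particle and the 7SK RNA, took 63.6% ± 2.42 of all TPM in sham, 0.772% ± 0.0708 in control oligo and 0.803% ± 0.0854 in knockdown libraries (SD, n = 3). Transcripts of the mitochondrial genome took 0.433% ± 0.150, 27.0% ± 2.08 and 24.5% ± 3.12. Nuclear protein-coding genes took 32.9% ± 2.01, 57.6% ± 3.16 and 61.3% ± 3.78, and pseudogenes 1.998% ± 0.153, 12.97% ± 1.42 and 11.8% ± 0.766. The 10 most abundant genes held 58.4 to 63.0% of TPM in sham and 21.6 to 27.8% in MCAO libraries. With this composition, the median gene was 0.56 (log2) higher in control oligo and 0.61 higher in knockdown than in sham libraries, and 0.06 higher in knockdown than in control oligo. Median-ratio scaling of the libraries moved the first pair of medians to 0.01 and 0.01, so list medians are also given relative to all genes (minus the all-gene median), and changes are also given scaled in this way.

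**Figure D1:**
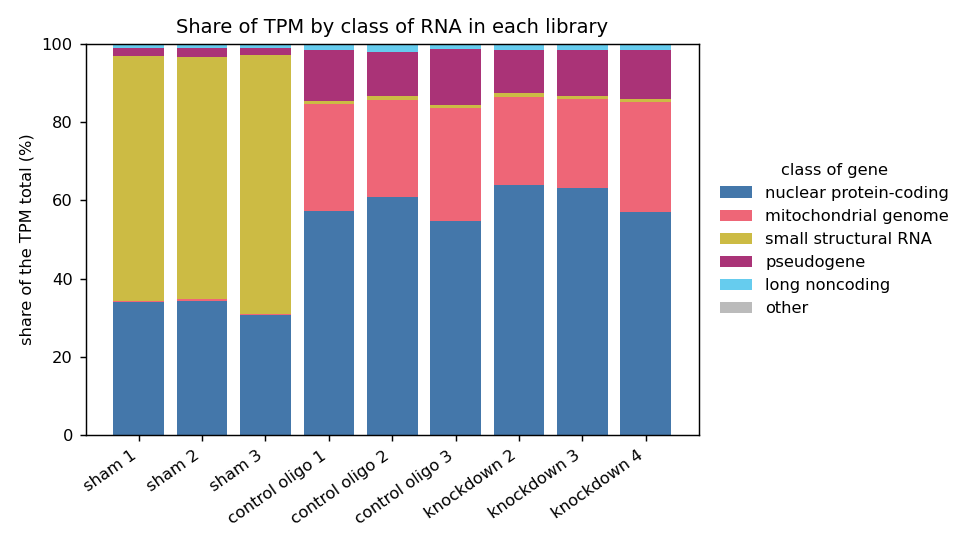
Share of all TPM (y axis, percent, stacked to the full total) by class of RNA in each of the 9 libraries (x axis). Small structural RNAs took 63.6% ± 2.42 in the sham libraries (SD, n = 3) and under 1% in each of the 6 MCAO libraries, where mitochondrial transcripts took 22.6 to 28.9%.

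The comparison of control oligo MCAO with sham cortex asked which transcripts differed in the infarcted cortex 6 h after reperfusion. Hspa1a and Hspa1b, near-identical inducible heat shock genes of the 70 kDa family whose reads could be split between them, stood at 486 ± 48.7 TPM against 4.24 ± 1.71 in sham (log2 change 6.58, 5.999 scaled) and at 504 ± 23.4 TPM against 4.67 ± 1.44 in sham (log2 change 6.50, 5.91 scaled). Atf3, a stress-induced transcription factor, stood at 72.0 ± 33.9 TPM against 0.334 ± 0.119 in sham (log2 change 5.65, 5.32 scaled), and Cdkn1a, an inhibitor of cyclin-dependent kinases, at 148 ± 9.61 TPM against 4.08 ± 0.812 in sham (log2 change 4.88, 4.30 scaled). The largest falls were those of small structural RNAs, among them Rn7s1, a 7SL RNA, at 36.1 ± 10.03 TPM against 189980.0 ± 10887 in sham (log2 change -12.36, -13.02 scaled).

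limma called 8990 genes higher and 2178 lower at an adjusted p under 0.05, or 11168 of 17080 with 80.5% higher. After median-ratio scaling 4456 were higher and 4983 lower (47.2% higher), of which 4456 higher and 2177 lower genes were called the same way without scaling and 30 called genes turned. The libraries of the 2 groups did not overlap for 12032 genes (70.4%, where chance gives 10%). Of the 40 gene lists tested 19 passed camera at the preset correlation, and 5 to 26 passed in the 9 other splits of the same 6 libraries into 3 and 3. Data set, read length, oligo (as described) and perhaps RNA selection cannot be told from stroke.

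Of the other genes named for the size of their rise, Lcn2, an iron-sequestering acute-phase protein, stood at 145 ± 77.4 TPM against 2.18 ± 0.859 in sham (log2 change 5.36, 4.84 scaled), Timp1, an inhibitor of matrix metalloproteinases, at 65.0 ± 36.9 TPM against 0.713 ± 0.520 in sham (log2 change 5.17, 4.78 scaled) and the chemokine Ccl3 at 48.4 ± 52.1 TPM against 0.0740 ± 0.0644 in sham (log2 change 4.97, 4.74 scaled). The metallothionein Mt2 stood at 1132 ± 282 TPM against 36.7 ± 8.27 in sham (log2 change 4.91, 4.25 scaled), and S100a8, a calcium-binding protein of neutrophils, at 79.1 ± 59.8 TPM against 0.958 ± 0.592 in sham (log2 change 4.80, 4.38 scaled). AY036118 (chromosome 17, 39847113 to 39848035) is annotated as long noncoding, with its read source untested. It had 4293, 7022 and 5044 TPM in control oligo and 0.0620, 58.1 and 0.0540 in sham (log2 change 10.37, 10.01 scaled).

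Most stress-response lists rose. Of the heat shock chaperones, 16 of 18 rose and 2 did not pass (median log2 change 1.83, 1.27 relative to all genes), and camera gave adjusted p = 0.000571 (adjusted p = 0.722 with an estimated correlation). After scaling 15 rose and 2 fell. Bag3, a co-chaperone, stood at 24.2 ± 1.14 TPM against 1.11 ± 0.326 in sham (log2 change 3.59, 3.14 scaled). Among unfolded protein response genes 17 of 20 rose, 1 fell and 2 did not pass (median log2 change 1.25, 0.69 relative to all genes), and camera gave adjusted p = 0.0131 (adjusted p = 0.722 with an estimated correlation). After scaling 12 rose and 3 fell. The transcription factors Ddit3 and Atf4 stood at 155 ± 41.7 TPM against 24.0 ± 1.48 in sham (log2 change 2.60, 1.95 scaled) and 292 ± 80.9 TPM against 55.4 ± 2.73 in sham (log2 change 2.34, 1.68 scaled). In the oxidative stress response 18 of 20 rose, 1 fell and 1 did not pass (median log2 change 1.34, 0.78 relative to all genes), and camera gave adjusted p = 0.0107 (adjusted p = 0.722 with an estimated correlation). After scaling 11 rose and 2 fell. Hmox1, the inducible heme oxygenase, stood at 90.2 ± 11.1 TPM against 2.34 ± 0.284 in sham (log2 change 4.77, 4.23 scaled). Of the immediate early genes, transcription factors and regulators induced within minutes of a stimulus, 20 of 25 rose and 5 did not pass (median log2 change 1.40, 0.84 relative to all genes), and camera gave adjusted p = 0.0160 (adjusted p = 0.722 with an estimated correlation). After scaling 11 rose and 1 fell. Without control oligo replicate 3 its adjusted p was 0.0530. Maff stood at 21.1 ± 5.63 TPM against 0.316 ± 0.150 in sham (log2 change 4.04, 3.74 scaled) and Fosb at 43.6 ± 20.4 TPM against 1.79 ± 0.526 in sham (log2 change 3.89, 3.38 scaled). Of the glucocorticoid-induced genes 12 of 15 rose and 3 did not pass (median log2 change 1.82, 1.26 relative to all genes), and camera gave adjusted p = 0.0107 (adjusted p = 0.722 with an estimated correlation). After scaling 11 rose and 1 fell. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 63.6 ± 14.7 TPM against 7.78 ± 1.49 in sham (log2 change 2.86, 2.25 scaled). In the hypoxia-induced list 13 of 19 rose and 6 did not pass (median log2 change 1.18, 0.61 relative to all genes), the camera adjusted p was 0.0597, and 10 rose and 2 fell after scaling. Leaving out control oligo replicate 2 gave adjusted p = 0.0393 (adjusted p = 0.659 with an estimated correlation). Ddit4 stood at 78.0 ± 10.6 TPM against 10.2 ± 1.56 in sham (log2 change 2.81, 2.18 scaled). Counts adjusted over the list alone were the same for these lists.

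Reactive astrocyte genes and most inflammatory lists were higher. All 21 pan-reactive astrocyte genes rose (median log2 change 2.38, 1.81 relative to all genes), and camera gave adjusted p = 3.38e-05 (adjusted p = 0.353 with an estimated correlation). After scaling 20 rose and 0 fell. Gfap and Vim, intermediate filaments of reactive astrocytes, stood at 475 ± 152 TPM against 28.7 ± 4.17 in sham (log2 change 3.96, 3.31 scaled) and 99.0 ± 23.2 TPM against 11.2 ± 1.33 in sham (log2 change 3.01, 2.38 scaled). Of the cytokines and chemokines 18 of 20 rose and 2 did not pass (median log2 change 2.08, 1.51 relative to all genes), and camera gave adjusted p = 0.0160 (adjusted p = 0.722 with an estimated correlation). After scaling 13 rose and 0 fell. Tnf stood at 2.27 ± 0.261 TPM against 0.0438 ± 0.0759 in sham (log2 change 1.65, 1.49 scaled) and the neutrophil chemoattractant Cxcl1 at 22.1 ± 18.0 TPM against 0.0896 ± 0.0977 in sham (log2 change 4.11, 3.89 scaled). Among NF-kB target and feedback genes 15 of 17 rose and 2 did not pass (median log2 change 1.56, 1.002 relative to all genes), and camera gave adjusted p = 0.0107 (adjusted p = 0.722 with an estimated correlation). After scaling 13 rose and 0 fell. The NF-kB subunit Relb stood at 12.3 ± 0.532 TPM against 1.28 ± 0.0982 in sham (log2 change 2.55, 2.08 scaled). In extracellular proteolysis 13 of 16 rose and 3 did not pass (median log2 change 1.58, 1.02 relative to all genes), and camera gave adjusted p = 0.0307 (adjusted p = 0.722 with an estimated correlation). After scaling 12 rose and 0 fell. Without control oligo replicate 3 this adjusted p was 0.102. Interferon-stimulated genes had 14 of 26 members higher, and camera gave adjusted p = 0.405 (median log2 change 1.28, 0.72 relative to all genes), with a median of 0.85 without control oligo replicate 1. After scaling 7 rose, with a camera adjusted p = 0.0370 (adjusted p = 0.795 with an estimated correlation). When adjusted over the list alone, 14 proteolysis and 13 interferon-stimulated genes rose, and the other counts were the same. Control oligo replicate 2 had the lowest mean log2(TPM + 1) of its group in the cytokine (2.42 against 3.52 and 3.93) and neutrophil lists (1.95 against 4.17 and 3.74).

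Pro-apoptotic genes were higher as a list. Among pro-apoptotic genes 16 of 21 rose and 5 did not pass (median log2 change 0.89, 0.33 relative to all genes), and camera gave adjusted p = 0.0243 (adjusted p = 0.722 with an estimated correlation). After scaling 10 rose and 1 fell. Tnfrsf1a, a receptor of tumor necrosis factor, stood at 40.3 ± 16.3 TPM against 2.46 ± 0.492 in sham (log2 change 3.52, 2.98 scaled) and Bak1, a mitochondrial pore former, at 24.3 ± 7.04 TPM against 4.23 ± 0.578 in sham (log2 change 2.24, 1.66 scaled). Of the anti-apoptotic genes 10 of 12 rose and 2 did not pass (median log2 change 0.92, 0.36 relative to all genes), and the list of 12 genes did not pass camera (adjusted p = 0.180), while 5 rose and 2 fell after scaling, and Mcl1 stood at 80.9 ± 11.3 TPM against 25.2 ± 1.35 in sham (log2 change 1.64, 0.99 scaled). In the p53 target list 10 of 14 rose, 1 fell and 3 did not pass (camera adjusted p = 0.211), and 5 rose and 2 fell after scaling. The blood-brain barrier list had 10 of 15 members higher and 1 lower, turning to 7 and 5 after scaling (camera adjusted p = 0.526), and its amino acid transporter Slc7a5 stood at 70.0 ± 25.99 TPM against 8.88 ± 1.19 in sham (log2 change 2.79, 2.17 scaled). These counts were the same adjusted over the list alone.

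Most receptor and channel genes of neurons that passed fell. Of the glutamate receptors 6 of 22 rose, 11 fell and 5 did not pass (median log2 change -0.44, -0.996 relative to all genes), and camera gave adjusted p = 0.000572 (adjusted p = 0.722 with an estimated correlation). After scaling 3 rose and 15 fell. The N-methyl-D-aspartate receptor subunit Grin2a stood at 17.8 ± 4.91 TPM against 97.0 ± 10.6 in sham (log2 change -2.41, -3.07 scaled) and the metabotropic receptor Grm5 at 18.1 ± 4.77 TPM against 83.5 ± 9.59 in sham (log2 change -2.17, -2.82 scaled), while the kainate receptor subunit Grik5 stood at 75.6 ± 17.4 TPM against 24.7 ± 2.09 in sham (log2 change 1.56, 0.91 scaled). Among GABA receptors 1 of 14 rose, 7 fell and 6 did not pass (median log2 change -0.30, -0.86 relative to all genes), and camera gave adjusted p = 0.00378 (adjusted p = 0.722 with an estimated correlation). After scaling 0 rose and 10 fell. Their median was -0.17 without control oligo replicate 3. Gabrb2 stood at 20.3 ± 8.05 TPM against 115 ± 11.3 in sham (log2 change -2.52, -3.17 scaled). In the potassium channels 6 of 25 rose, 13 fell and 6 did not pass (median log2 change -0.74, -1.30 relative to all genes), and camera gave adjusted p = 0.000295 (adjusted p = 0.722 with an estimated correlation). After scaling 4 rose and 17 fell. Kcnh7 stood at 10.8 ± 2.97 TPM against 53.7 ± 6.35 in sham (log2 change -2.24, -2.88 scaled). Presynaptic and vesicle genes went both ways, 13 of 20 rose, 3 fell and 4 did not pass, with a median of 0.68 that became 0.02 after scaling (7 rose and 7 fell) and turned to -0.12 with TPM recomputed over nuclear protein-coding genes. Camera gave adjusted p = 0.275 for it, and the vesicle protein Vamp2 stood at 1012 ± 57.1 TPM against 132 ± 14.8 in sham (log2 change 2.94, 2.27 scaled). Of the neurotrophic factors and neuropeptides 12 of 16 rose and 4 did not pass (camera adjusted p = 0.105), and 6 rose and 0 fell after scaling, while without control oligo replicate 1 camera gave adjusted p = 0.0416 (adjusted p = 0.742 with an estimated correlation). With p adjusted over the list alone, 14 potassium channels fell, and the other counts were the same.

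Genes of protein synthesis and energy metabolism were higher. All 35 cytosolic ribosomal proteins rose (median log2 change 1.46, 0.89 relative to all genes), and camera gave adjusted p = 3.36e-08 (adjusted p = 0.722 with an estimated correlation). After scaling 29 rose and 0 fell. Rps2 stood at 432 ± 25.9 TPM against 95.1 ± 5.90 in sham (log2 change 2.17, 1.51 scaled). Of the nuclear-encoded respiratory chain genes 30 of 31 rose and 1 did not pass (median log2 change 1.009, 0.45 relative to all genes), and camera gave adjusted p = 0.000295 (adjusted p = 0.722 with an estimated correlation). After scaling 9 rose and 2 fell. Cox5a, a subunit of cytochrome c oxidase, stood at 278 ± 26.4 TPM against 106 ± 2.84 in sham (log2 change 1.38, 0.71 scaled). With TPM recomputed over nuclear protein-coding genes the respiratory chain list had adjusted p = 0.203 and cholesterol biosynthesis adjusted p = 0.0512. Among the enzymes of cholesterol biosynthesis 18 of 20 rose and 2 did not pass (median log2 change 1.09, 0.53 relative to all genes), and camera gave adjusted p = 0.0131 (adjusted p = 0.722 with an estimated correlation). After scaling 9 rose and 2 fell. Pmvk, phosphomevalonate kinase, stood at 89.2 ± 7.11 TPM against 25.7 ± 3.56 in sham (log2 change 1.76, 1.11 scaled). All 13 mitochondrially encoded genes rose (median log2 change 7.22, 6.66 relative to all genes), and camera gave adjusted p = 3.39e-09 (adjusted p = 0.722 with an estimated correlation). After scaling 13 rose and 0 fell. mt-Nd4 stood at 12998 ± 1009 TPM against 49.2 ± 11.7 in sham (log2 change 8.04, 7.38 scaled), with the caveat that reads could be shared with nuclear copies of the mitochondrial genome. Adjusted over the list alone, the counts of these lists were the same.

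Histone and structural RNA genes fell, and most of their transcripts have no poly(A) tail. Of the replication-dependent histones 1 of 21 rose, 18 fell and 2 did not pass (median log2 change -2.26, -2.82 relative to all genes), and camera gave adjusted p = 1.00e-16 (adjusted p = 0.353 with an estimated correlation). After scaling 0 rose and 18 fell. Hist1h4d stood at 0.268 ± 0.259 TPM against 40.3 ± 10.1 in sham (log2 change -5.01, -5.49 scaled). In the list of short structural noncoding RNAs 13 of 14 fell and 1 did not pass (median log2 change -8.25, -8.81 relative to all genes), and camera gave adjusted p = 4.07e-23 (adjusted p = 0.0299 with an estimated correlation). After scaling 0 rose and 13 fell. Only this list kept its call with an estimated correlation, and lost it there after scaling (adjusted p = 0.368) and without any 1 of the libraries (adjusted p = 0.0520 or more). The other structural RNAs named for the size of their fall were Rn7s6 (log2 change -12.89), Rn7s2 (-11.90), Rpph1 (-11.31), Rmrp (-9.39), Rn7sk (-8.97), Rny1 (-8.95), Snora74a (-8.58) and Rnu2-10 (-8.18). Rny3, a Y RNA, was listed at 0 in all 6 MCAO libraries and at 1186, 953 and 966 TPM in sham replicates 1, 2 and 3. Both sets of counts were the same adjusted over the list alone.

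Markers of the cell types that cortex could hold did not pass as lists under camera, and the pairs of scaled counts are those higher and lower. Microglial markers had 12 of 16 higher and 1 lower (adjusted p = 0.196), and 9 and 2 after scaling. Neutrophil markers had 10 of 11 higher (adjusted p = 0.0837), and after scaling 9 rose, and camera gave adjusted p = 0.00299 (adjusted p = 0.579 with an estimated correlation). Leaving out control oligo replicate 2, the neutrophil median of 1.69 became 2.36 with adjusted p = 0.000799 (adjusted p = 0.659 with an estimated correlation). Monocyte and macrophage markers had 9 of 13 higher (adjusted p = 0.275), which became 5 and 1 after scaling with adjusted p = 0.0377 (adjusted p = 0.659 with an estimated correlation). Excitatory neuron markers had 8 of 14 higher and 4 lower (adjusted p = 0.972, 6 and 5 scaled) and inhibitory neuron markers 11 of 14 higher and 2 lower (adjusted p = 0.284, 5 and 2 scaled). Astrocyte markers had 8 of 14 higher and 1 lower (adjusted p = 0.533, 3 and 4 scaled), oligodendrocyte markers 9 of 14 higher and 1 lower (adjusted p = 0.599, 2 and 2 scaled) and their precursors 7 of 12 higher and 1 lower (adjusted p = 0.781, 3 and 3 scaled). Endothelial markers had 8 of 14 higher and 2 lower (adjusted p = 0.781), 3 and 5 scaled, and their median of 0.64 turned to -0.14 over nuclear protein-coding genes. Pericyte and smooth muscle markers had 6 of 12 higher (adjusted p = 0.764), 3 and 3 scaled, with a median of 0.53 that turned to -0.10 in the same way. Choroid plexus and ependyma had 4 of 5 higher (adjusted p = 0.230, 3 and 0 scaled), which became adjusted p = 0.0402 (adjusted p = 0.509 with an estimated correlation) over nuclear protein-coding genes. Striatal markers had 8 of 14 higher and 1 lower (adjusted p = 0.526, 6 and 2 scaled), and meningeal and fibroblast markers 7 of 14 higher (adjusted p = 0.764, 4 and 3 scaled). Erythroid markers had 2 of 7 higher (adjusted p = 0.852, 1 and 0 scaled), with a median of 0.83 and a mean of 0.51 although camera tested in the other direction, and a median of -0.04 without control oligo replicate 3. Lymphocyte markers kept 3 genes, too few for the test, of which 1 rose, and their median of 0.42 turned to -0.22 after scaling. When adjusted over the list alone, 11 neutrophil and 5 pericyte markers rose, and the other counts were the same.

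**Figure D2:**
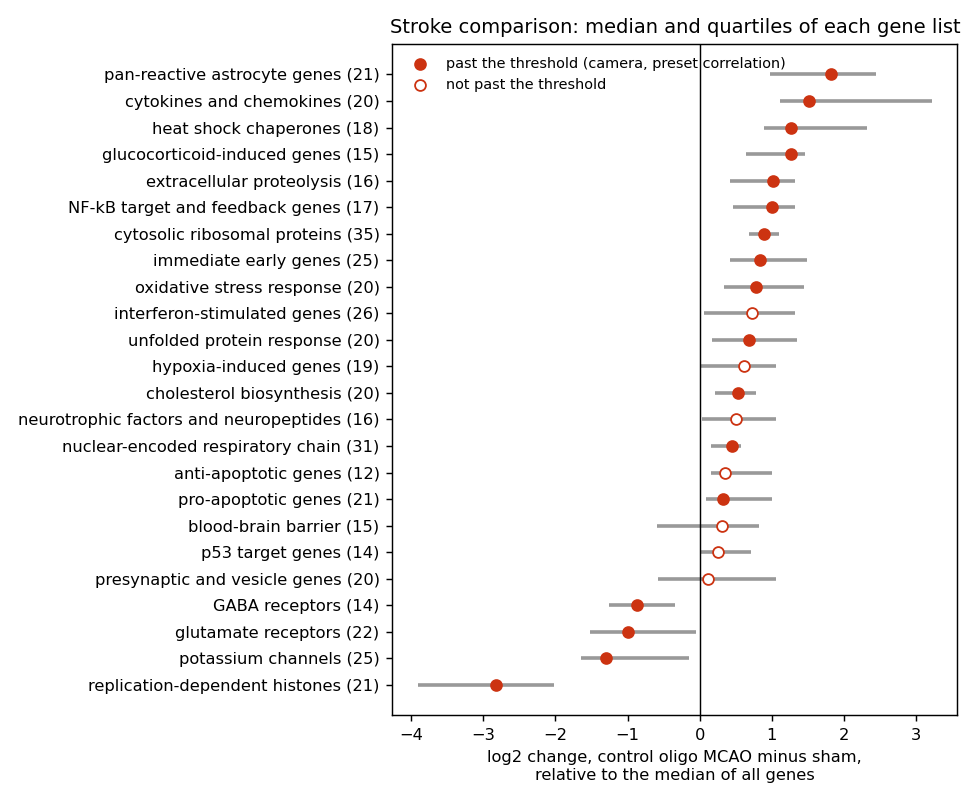
Median (point) and quartiles (line) of the log2 change, control oligo MCAO minus sham (x axis), over the members of each of 24 gene lists (y axis), relative to the all-gene median of 0.56; filled points passed camera with the preset correlation and open points did not, and the mitochondrially encoded and short structural lists are left out for scale. Pan-reactive astrocyte genes lay at 1.81, potassium channels at -1.30 and replication-dependent histones at -2.82.

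The comparison of knockdown with control oligo, both after MCAO and from 1 data set, asked what lowering eRNA_06347 changed in the infarcted cortex. The position of eRNA_06347 was not given in the sources used here, so its level was not analysed here and the group labels were not checked by it. A mitochondrial serine transfer RNA fell and a pseudogene rose, and no gene of the 41 fixed lists passed on its own. mt-Ts2 (59 nt, mitochondrial genome 11613 to 11671) had 0.609, 0.683 and 0.814 TPM in the knockdown libraries and 125, 141 and 125 in the control oligo libraries, a log2 change of -6.27 (SE 0.166, limma adjusted p = 9.02e-05). Gm7808, a processed pseudogene of 387 nt on chromosome 9 (19927896 to 19928282, GRCm38), had 10.2, 12.02 and 8.53 TPM in the knockdown libraries and was listed at 0 in all control oligo and sham libraries (limma adjusted p = 0.00317).

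limma called 1 gene higher and 1 lower of 17080, and 321 had an unadjusted p under 0.05 where chance gives 854. The libraries of the 2 groups did not overlap for 923 genes (5.40%, where chance gives 10%). With weights on estimated read pairs (voom) limma called 4 genes, with all 9 libraries in 1 fit 4, and without a filter on low values 7. Gm7808 lost its call without control oligo replicate 1 (adjusted p = 0.0808), replicate 2 (0.0874) and replicate 3 (0.0524). With the replicate number as a block, mt-Ts2 had a log2 change of -6.35 (SE 0.229, adjusted p = 0.168) and Gm7808 one of 3.60 (SE 0.212, adjusted p = 0.400), against 3.48 (SE 0.176) without it. Both calls were lost, as only replicates 2 and 3 of each group enter the folds. Both features are named because the count was 5 or fewer, after their values were seen. mt-Ts2 is shorter than a read pair and Gm7808 is a processed pseudogene, so both values are uncertain.

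The genes of smallest p in each direction did not pass. Nup62, a protein of the nuclear pore on chromosome 7 (44816088 to 44830812), stood at 34.5 ± 5.49 TPM against 4.55 ± 1.54 in control oligo (log2 change 2.70, 2.62 scaled) with limma adjusted p = 0.152, and at 9.08, 9.32 and 8.98 in sham replicates 1, 2 and 3. It passed after median-ratio scaling (adjusted p = 0.0495), with a mean TPM of 5 or more (0.0464), with voom (0.0224) and with all 9 libraries in 1 fit, and in no fit that left out a library (adjusted p 0.145 to 0.692). The others higher were Rflna (log2 change 0.77), Rpa1 (0.96), H3f3a (0.67) and Tsc22d3, the glucocorticoid-induced leucine zipper, at 100.5 ± 18.0 TPM against 50.3 ± 9.79 in control oligo (log2 change 0.99, 0.93 scaled). The lower ones were Mir719 (-0.94), Cap1 (-0.85), Mcmdc2 (-0.71) and Snora73b (-1.06). Limma gave these 8 genes adjusted p of 0.766 to 1.

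As lists, 9 passed camera, 5 higher and 4 lower, with median log2 changes between -0.26 and 0.38 and 0 members past the threshold over all genes tested. With an estimated correlation 0 lists passed, and at the preset correlation the 9 other splits of the same 6 libraries into 3 and 3 passed 9 to 28 lists. Unfolded protein response genes were higher as a list, with a median log2 change of 0.29 (0.24 scaled), and camera gave adjusted p = 0.000208 (adjusted p = 0.990 with an estimated correlation). Dnajb9, a chaperone of the endoplasmic reticulum, was at 74.4 ± 5.98 TPM against 57.0 ± 8.49 in control oligo (log2 change 0.39, 0.33 scaled). The short structural noncoding RNAs were lower as a list at -0.26 (-0.25 scaled), and camera gave adjusted p = 0.000458 (adjusted p = 0.432 with an estimated correlation). Both lists still passed at the preset correlation when any single library was left out, but the unfolded protein response median was 0.16 without control oligo replicate 3 and 0.17 without knockdown replicate 2, and that of the structural RNAs -0.16 without control oligo replicate 3 and -0.11 without knockdown replicate 3. Microglial markers were higher at 0.38 (0.32 scaled), and camera gave adjusted p = 0.0338 (adjusted p = 0.990 with an estimated correlation). Without knockdown replicate 4 the microglial median was 0.01 (adjusted p = 0.974), without control oligo replicate 2 the adjusted p was 0.153, and without control oligo replicate 3 the median was 0.23. Trem2, a microglial receptor, was at 25.6 ± 3.44 TPM against 18.7 ± 2.28 in control oligo (log2 change 0.44, 0.38 scaled). The oxidative stress list was higher at 0.25 (0.20 scaled), and camera gave adjusted p = 0.0217 (adjusted p = 0.990 with an estimated correlation), which became 0.280 without control oligo replicate 2 and 0.498 without knockdown replicate 4 (median 0.12). Cytosolic ribosomal proteins lay at 0.11 (0.06 scaled, adjusted p = 0.227), and camera gave adjusted p = 0.0392 (adjusted p = 0.990 with an estimated correlation), which became 0.262 without control oligo replicate 2 (median 0.03) and 0.998 without knockdown replicate 3 (0.05), with a median of 0.19 without control oligo replicate 3 and 0.17 without knockdown replicate 4. Replication-dependent histones lay at 0.13 (0.11 scaled), and camera gave adjusted p = 0.0338 (adjusted p = 0.767 with an estimated correlation), which became 0.480 without control oligo replicate 2 and 0.136 without knockdown replicate 4, with a median of 0.08 without knockdown replicate 2.

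The glutamate receptor and potassium channel lists were lower by small amounts. Glutamate receptors lay at -0.08 (-0.13 scaled), and camera gave adjusted p = 0.0338 (adjusted p = 0.990 with an estimated correlation). Without knockdown replicate 4 their median turned to 0.05 (adjusted p = 0.805), and without control oligo replicate 2 the adjusted p was 0.190 at a median of 0.00. The glutamate receptor median was -0.17 without control oligo replicate 3 and -0.14 without knockdown replicate 2. Gria3 was at 38.7 ± 5.75 TPM against 50.4 ± 6.67 in control oligo (log2 change -0.38, -0.43 scaled). Potassium channels lay at -0.08 (-0.13 scaled), and camera gave adjusted p = 0.0439 (adjusted p = 0.990 with an estimated correlation). Their adjusted p became 0.164 and 0.272 without control oligo replicates 1 and 2, and 0.188 and 0.586 without knockdown replicates 3 and 4, with medians that turned to 0.04 without control oligo replicate 2 and 0.07 without knockdown replicate 4. They were -0.16 without control oligo replicate 3 and -0.22 without knockdown replicate 2. Mitochondrially encoded genes lay at -0.20 (-0.26 scaled, adjusted p = 0.178), and camera gave adjusted p = 0.0217 (adjusted p = 0.990 with an estimated correlation), which became 0.0994 and 0.364 without control oligo replicates 1 and 3 and 0.170 without knockdown replicate 2, with medians of -0.13 and -0.11 in the latter pair. mt-Nd4 was at 9807 ± 1567 TPM against 12998 ± 1009 in control oligo (log2 change -0.42, -0.47 scaled). Adjusted over the list alone, 1 glucocorticoid-induced gene (Tsc22d3) rose and 2 short structural noncoding RNAs fell, and no other gene of the tested lists passed.

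Inflammatory lists did not pass, and 1 library stood apart in them. Camera gave medians of -0.10 (adjusted p = 0.417) for cytokines and chemokines, whose mean was 0.00, 0.00 (adjusted p = 0.748) for NF-kB genes, 0.13 (adjusted p = 0.957) for interferon-stimulated genes, 0.23 (adjusted p = 0.358) for pan-reactive astrocyte genes and 0.10 (adjusted p = 0.760) for extracellular proteolysis. For NF-kB genes the median turned to -0.04 after scaling, and for interferon-stimulated and proteolysis genes the test pointed lower. Neutrophil markers lay at 0.45 (adjusted p = 0.760) and monocyte and macrophage markers at 0.58 (adjusted p = 0.259). In knockdown replicate 4 the mean log2(TPM + 1) exceeded that of the other 5 MCAO libraries by 2.98 over neutrophil markers, 2.68 over monocyte and macrophage markers, 2.13 over cytokines, 2.10 over interferon-stimulated genes, 1.75 over pan-reactive astrocyte genes, 1.47 over NF-kB genes, 1.299 over proteolysis genes and 0.75 over microglial markers. Its excess was 1.18 over endothelial, 0.92 over meningeal and fibroblast, and 0.70 over pericyte and smooth muscle markers. Il1b had 116 TPM in this library, 3.95 and 1.97 in knockdown replicates 2 and 3, and 4.05, 1.37 and 10.5 in the control oligo libraries. Without knockdown replicate 4 camera called 15 lists. Those of this paragraph (adjusted p in brackets) were cytokines at -1.12 (6.86e-06), NF-kB genes at -0.37 (0.000475), interferon-stimulated genes at -0.73 (1.72e-07), pan-reactive astrocyte genes at -0.43 (1.95e-05), proteolysis genes at -0.50 (0.000165), neutrophil markers at -0.66 (0.000419) and monocyte markers at -0.66 (0.000713), where the smallest adjusted p with an estimated correlation was 0.533. With 25 and 21 lists past the threshold without knockdown replicates 2 and 3, the calls gained here were, at these medians, NF-kB genes (0.24 and 0.38), interferon-stimulated genes (0.50 and 0.59), pan-reactive astrocyte genes (0.61 and 0.57), neutrophil markers (1.12 and 1.04) and monocyte markers (1.03 and 0.98), where the smallest adjusted p with an estimated correlation was 0.700 and 0.930. Control oligo replicates 1, 2 and 3 left out gave 13, 10 and 12 lists, and calls to interferon-stimulated genes (0.63) and monocyte markers (0.66) in the first case, cytokines (-0.48), interferon-stimulated genes (-0.17) and proteolysis genes (-0.19) in the second, and NF-kB genes (0.30) in the third, with smallest adjusted p of 0.763, 0.829 and 0.670 at an estimated correlation.

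**Figure D3:**
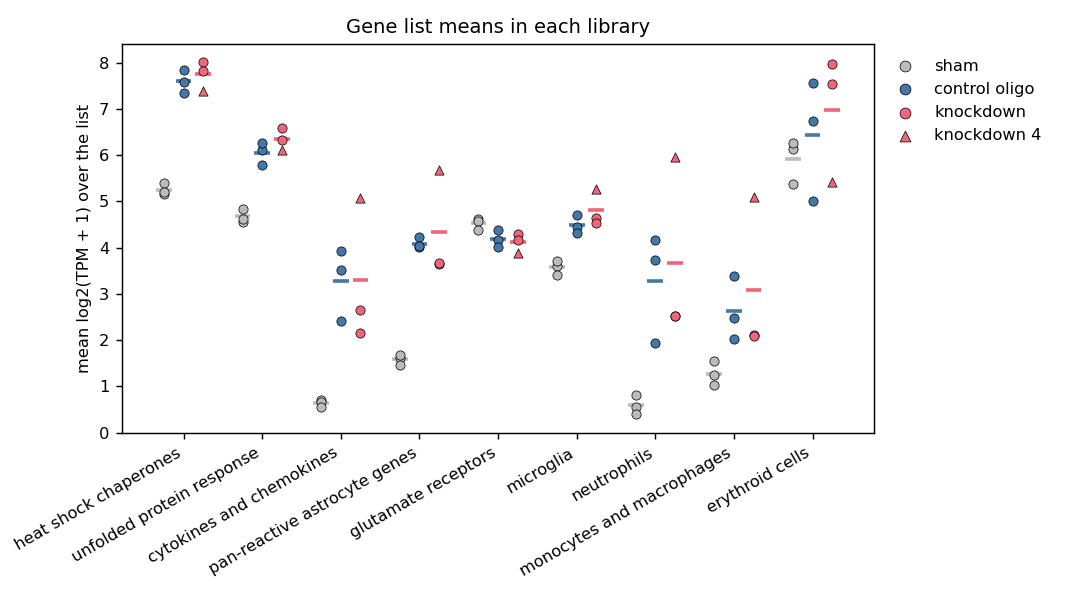
Mean log2(TPM + 1) over the members of 9 gene lists (y axis) in each library of the 3 groups (x axis); points are libraries, bars are group means and the triangle is knockdown replicate 4. This library lay at 5.96 over neutrophil markers, where the other 5 MCAO libraries ran from 1.95 to 4.17.

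The remaining lists did not pass under camera, and their medians are given here with the adjusted p. Heat shock chaperones lay at 0.18 (adjusted p = 0.417), immediate early genes at -0.06 (adjusted p = 0.0697), glucocorticoid-induced genes at 0.04 (adjusted p = 0.912) and hypoxia-induced genes at 0.07 (adjusted p = 0.912). Pro-apoptotic genes lay at 0.14 (adjusted p = 0.202), anti-apoptotic genes at 0.13 (adjusted p = 0.808), p53 targets at 0.12 (adjusted p = 0.760) and blood-brain barrier genes at 0.28 (adjusted p = 0.0973). GABA receptors lay at 0.02 (adjusted p = 0.938), presynaptic and vesicle genes at -0.08 (adjusted p = 0.101), which passed after scaling with adjusted p = 0.0434 (adjusted p = 0.978 with an estimated correlation), and neurotrophic factors and neuropeptides at -0.05 (adjusted p = 0.0749). Cholesterol biosynthesis lay at 0.01 (adjusted p = 0.912) and the nuclear-encoded respiratory chain at 0.01 (adjusted p = 0.417). After scaling the medians of glucocorticoid-induced genes (-0.01), GABA receptors (-0.04), cholesterol biosynthesis (-0.05) and the respiratory chain (-0.04) lay below 0, as their tests did without scaling, and the respiratory chain mean was -0.00360. Of the cell types, excitatory neuron markers lay at 0.03 (adjusted p = 0.497), turning to -0.02 scaled, inhibitory neuron markers at -0.06 (adjusted p = 0.497), astrocyte markers at 0.08 (adjusted p = 0.940), oligodendrocyte markers at 0.09 (adjusted p = 0.977) and their precursors at -0.01 (adjusted p = 0.940) with a mean of 0.03. The excitatory neuron and oligodendrocyte tests pointed lower. Endothelial markers lay at 0.25 (adjusted p = 0.158), pericyte and smooth muscle markers at 0.21 (adjusted p = 0.248), choroid plexus and ependyma at 0.43 (adjusted p = 0.299), striatum at -0.07 (adjusted p = 0.555), meninges and fibroblasts at 0.23 (adjusted p = 0.259) and erythroid cells at 0.80 (adjusted p = 0.677). The 3 lymphocyte markers kept had a median of -0.27 (0.07 without knockdown replicate 4) and were not tested as a list. Counts of members that rose or fell were 0 for each of these lists. With TPM recomputed over nuclear protein-coding genes, calls were gained by immediate early genes (0.0309), presynaptic and vesicle genes (0.00738), neurotrophic factors and neuropeptides (0.0309) and the respiratory chain (0.0298), all lower and with adjusted p = 0.944 at an estimated correlation.

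Leaving out single libraries changed medians and calls of these lists. Of all 31 lists that did not pass, 26 had a median that turned in sign without 1 of the libraries, 16 of them without knockdown replicate 4. In the fit without knockdown replicate 4, calls (adjusted p in brackets) were gained by heat shock chaperones at 0.40 (0.00349), cholesterol biosynthesis genes at 0.21 (0.0463), respiratory chain genes at 0.17 (0.00120) and erythroid markers at 1.83 (0.0130), and medians turned in anti-apoptotic genes (-0.03), glucocorticoid-induced genes (-0.04), presynaptic genes (0.12), neurotrophic and neuropeptide genes (0.17), inhibitory neuron markers (0.17), oligodendrocyte precursor markers (0.14), endothelial markers (-0.18), pericyte markers (-0.06), striatal markers (0.14) and meningeal markers (-0.11). Without knockdown replicates 2 and 3 in turn, calls were gained at these medians by blood-brain barrier genes (0.37 and 0.37), presynaptic genes (-0.21 and -0.15), neurotrophic and neuropeptide genes (-0.18 and -0.28), respiratory chain genes (-0.07 and -0.08), endothelial markers (0.52 and 0.47), pericyte markers (0.32 and 0.28) and meningeal markers (0.45 and 0.39). Further calls were those of immediate early genes (-0.04), excitatory neuron markers (-0.10), inhibitory neuron markers (-0.19), choroid plexus markers (0.76) and striatal markers (-0.13) without replicate 2, and pro-apoptotic genes (0.22) and cholesterol biosynthesis genes (-0.08) without replicate 3. Of the control oligo libraries, replicate 1 left out gave calls to pro-apoptotic genes (0.23), blood-brain barrier genes (0.33), neurotrophic and neuropeptide genes (-0.21) and meningeal markers (0.46), replicate 2 to immediate early genes (-0.19), neurotrophic and neuropeptide genes (-0.16), respiratory chain genes (-0.06) and inhibitory neuron markers (-0.09), and replicate 3 to oligodendrocyte markers (0.22), endothelial markers (0.39) and erythroid markers (1.64). With an estimated correlation 0 of all lists passed in any of these fits, at a smallest adjusted p of 0.533.

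The comparison of knockdown MCAO with sham cortex asked how the infarcted cortex with the knockdown differed from healthy cortex. Hspa1a and Hspa1b stood at 412 ± 176 TPM against 4.24 ± 1.71 in sham (log2 change 6.27, 5.63 scaled) and 448 ± 177 TPM against 4.67 ± 1.44 in sham (log2 change 6.27, 5.62 scaled), and Atf3 at 91.9 ± 18.4 TPM against 0.334 ± 0.119 in sham (log2 change 6.11, 5.73 scaled). Hmox1, the inducible heme oxygenase, stood at 289 ± 296 TPM against 2.34 ± 0.284 in sham (log2 change 5.96, 5.36 scaled), Lcn2 at 355 ± 470.4 TPM against 2.18 ± 0.859 in sham (log2 change 5.91, 5.33 scaled) and the neutrophil protein S100a9 at 295 ± 431 TPM against 2.41 ± 1.299 in sham (log2 change 5.23, 4.66 scaled), each with an SD set by knockdown replicate 4. With voom S100a9 (log2 change 5.14, adjusted p = 0.0566) and S100a8 (5.57, 0.0566) lost their calls, with an SE of 1.89 and 2.05 against 1.02 and 1.03 without weights. The largest falls were again those of small structural RNAs, with Rn7s1 at 21.9 ± 2.77 TPM against 189980.0 ± 10887 in sham (log2 change -13.02, -13.73 scaled).

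limma called 9007 genes higher and 2143 lower (11150, 80.8% higher). After median-ratio scaling 3883 were higher and 4629 lower (45.6% higher), and 46 called genes turned. Groups did not overlap for 12311 genes (72.1%, by chance 10%), and data set, oligo and stroke cannot be told apart either. Camera passed 17 lists, and 18 to 24 in the 9 other splits of these libraries. The other genes named for the size of their rise were S100a8 (log2 change 5.18), Timp1 (5.14), Ccl3 (4.94) and AY036118 (10.28). Among those named for their fall were Rn7s6 (-13.23), Rn7s2 (-12.90), Rpph1 (-11.58), Rmrp (-10.25), Rn7sk (-10.02), Rny1 (-9.20), Rnu2-10 (-8.84) and Snora74a (-8.69), while Rny3 was listed at 0 in the knockdown libraries.

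Stress lists were higher, at medians relative to all genes of 1.48 for heat shock chaperones, 0.89 for the unfolded protein response and 0.78 for the oxidative stress response. Of the heat shock chaperones 16 of 18 rose and 2 did not pass (median log2 change 2.10, 13 rose and 2 fell scaled), and camera gave adjusted p = 0.00264 (adjusted p = 0.933 with an estimated correlation). Among unfolded protein response genes 17 of 20 rose and 3 did not pass (median log2 change 1.51, 13 rose and 2 fell scaled), and camera gave adjusted p = 0.00310 (adjusted p = 0.961 with an estimated correlation). Atf4 stood at 367 ± 86.7 TPM against 55.4 ± 2.73 in sham (log2 change 2.68, 1.96 scaled). In the oxidative stress response 17 of 20 rose and 3 did not pass (median log2 change 1.40, 13 rose and 1 fell scaled), and camera gave adjusted p = 0.0149 (adjusted p = 0.933 with an estimated correlation). Of the immediate early genes 20 of 25 rose and 5 did not pass (median log2 change 1.302, 10 rose and 0 fell scaled), and camera gave adjusted p = 0.0205 (adjusted p = 0.961 with an estimated correlation), which became 0.0721 without knockdown replicate 4. Jun stood at 133 ± 20.6 TPM against 10.5 ± 0.546 in sham (log2 change 3.53, 2.85 scaled). For glucocorticoid-induced genes 14 of 15 rose and 1 did not pass (median log2 change 1.72, 9 rose and 0 fell scaled), and camera gave adjusted p = 0.00896 (adjusted p = 0.933 with an estimated correlation). Hypoxia-induced genes held a list call too, as 15 of 19 rose and 4 did not pass (median log2 change 1.11, 10 rose and 2 fell scaled), and camera gave adjusted p = 0.0292 (adjusted p = 0.933 with an estimated correlation). For pro-apoptotic genes 18 of 21 rose and 3 did not pass (median log2 change 1.13, 9 rose and 2 fell scaled), and camera gave adjusted p = 0.0232 (adjusted p = 0.933 with an estimated correlation). Of the anti-apoptotic genes 7 of 12 rose and 5 did not pass (3 rose and 2 fell scaled, adjusted p = 0.576) and of the p53 targets 10 of 14 rose and 4 did not pass (5 rose and 2 fell scaled, adjusted p = 0.164) under camera. With p adjusted over the list alone, 18 unfolded protein response, 19 pro-apoptotic and 4 anti-apoptotic genes rose, 1 hypoxia-induced gene fell, and the other counts were the same.

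Pan-reactive astrocyte genes were higher, as 20 of 21 rose and 1 did not pass (median log2 change 2.23, 16 rose and 0 fell scaled), and camera gave adjusted p = 0.0104 (adjusted p = 0.961 with an estimated correlation). S100a10 stood at 120.5 ± 15.7 TPM against 37.7 ± 3.92 in sham (log2 change 1.64, 0.93 scaled). The more variable inflammatory lists did not pass camera without scaling and with all libraries. Of the cytokines and chemokines 15 of 20 rose and 5 did not pass (10 rose and 0 fell scaled, adjusted p = 0.102), with adjusted p = 0.000407 after scaling, 0.0118 without knockdown replicate 3 and 0.0245 without replicate 4. Among NF-kB genes 11 of 17 rose and 6 did not pass (9 rose and 0 fell scaled, adjusted p = 0.112), with 0.00299 after scaling, 0.0416 without knockdown replicate 2 and 0.0228 without replicate 3, and in extracellular proteolysis 11 of 16 rose and 5 did not pass (7 rose and 0 fell scaled, adjusted p = 0.147), with 0.00554 after scaling and 0.0349 without knockdown replicate 3. With an estimated correlation each of these 3 lists had adjusted p = 0.688 after scaling, and adjusted p = 0.643 to 0.919 with the libraries left out. Ccl12, a monocyte chemoattractant, stood at 35.3 ± 33.3 TPM against 0.291 ± 0.0537 in sham (log2 change 4.43, 4.07 scaled) and Relb at 12.4 ± 1.64 TPM against 1.28 ± 0.0982 in sham (log2 change 2.55, 2.03 scaled). Of the interferon-stimulated genes 9 of 26 rose and 17 did not pass (3 rose and 0 fell scaled, adjusted p = 0.752), and of the blood-brain barrier genes 10 of 15 rose and 5 did not pass (6 rose and 3 fell scaled, adjusted p = 0.384). When adjusted over the list alone, 7 interferon-stimulated genes rose, and the other counts were the same.

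Neuronal receptor and channel lists were lower, at medians relative to all genes of -1.19 for glutamate receptors and -1.41 for potassium channels. Of the glutamate receptors 6 of 22 rose, 12 fell and 4 did not pass (median log2 change -0.58, 3 rose and 15 fell scaled), and camera gave adjusted p = 0.000233 (adjusted p = 0.933 with an estimated correlation). Among potassium channels 6 of 25 rose, 14 fell and 5 did not pass (median log2 change -0.80, 2 rose and 17 fell scaled), and camera gave adjusted p = 3.23e-05 (adjusted p = 0.933 with an estimated correlation). For GABA receptors 1 of 14 rose, 4 fell and 9 did not pass (median log2 change -0.25, 0 rose and 10 fell scaled), and camera gave adjusted p = 0.00264 (adjusted p = 0.961 with an estimated correlation), with a median of -0.14 without sham replicate 2. Grin2a stood at 16.0 ± 1.02 TPM against 97.0 ± 10.6 in sham (log2 change -2.53, -3.23 scaled), Kcnh7 at 10.7 ± 2.18 TPM against 53.7 ± 6.35 in sham (log2 change -2.23, -2.92 scaled) and Gabrb2 at 24.7 ± 4.49 TPM against 115 ± 11.3 in sham (log2 change -2.18, -2.89 scaled). Presynaptic and vesicle genes went both ways, 11 of 20 rose, 3 fell and 6 did not pass, with a median of 0.63 that turned to -0.09 scaled (7 rose and 6 fell, camera adjusted p = 0.829). Of the neurotrophic factors and neuropeptides 10 of 16 rose and 6 did not pass (3 rose and 2 fell scaled, adjusted p = 0.342) under camera. Adjusted over the list alone, 0 GABA receptor genes rose and 3 fell, 12 presynaptic genes rose, and the other counts were the same.

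Ribosomal, mitochondrial and sterol genes were higher and tail-less RNAs lower. All 35 cytosolic ribosomal proteins rose (median log2 change 1.60, 30 rose and 1 fell scaled), and camera gave adjusted p = 1.37e-07 (adjusted p = 0.933 with an estimated correlation). Rps2 stood at 496 ± 49.1 TPM against 95.1 ± 5.90 in sham (log2 change 2.37, 1.65 scaled). Of the nuclear-encoded respiratory chain 27 of 31 rose and 4 did not pass (median log2 change 0.91, 10 rose and 4 fell scaled), and camera gave adjusted p = 0.00896 (adjusted p = 0.961 with an estimated correlation), which became 0.107 after scaling. Among cholesterol biosynthesis genes 18 of 20 rose and 2 did not pass (median log2 change 1.04, 7 rose and 1 fell scaled), and camera gave adjusted p = 0.0339 (adjusted p = 0.961 with an estimated correlation), which became 0.0541 without sham replicate 2. With TPM recomputed over nuclear protein-coding genes the adjusted p of cholesterol biosynthesis was 0.0947 and that of hypoxia-induced genes 0.0552. All 13 mitochondrially encoded genes rose (median 6.91, 13 rose and 0 fell scaled), and camera gave adjusted p = 1.37e-07 (adjusted p = 0.933 with an estimated correlation). Of the replication-dependent histones 2 of 21 rose, 18 fell and 1 did not pass (median log2 change -2.40, 0 rose and 18 fell scaled), and camera gave adjusted p = 7.93e-15 (adjusted p = 0.542 with an estimated correlation). In the list of short structural noncoding RNAs 13 of 14 fell and 1 did not pass (median log2 change -8.47, 0 rose and 13 fell scaled), and camera gave adjusted p = 6.27e-23 (adjusted p = 0.104 with an estimated correlation). Adjusted over the list alone, 14 short structural noncoding RNAs fell, and the other counts were the same.

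Cell type markers did not pass as lists under camera in this comparison either. Microglial markers had 12 of 16 higher and 1 lower (adjusted p = 0.285, 7 and 1 scaled), with Fcrls at 49.9 ± 4.87 TPM against 12.2 ± 1.47 in sham (log2 change 1.95, 1.27 scaled). Neutrophil markers had 7 of 11 higher (adjusted p = 0.342, 5 and 0 scaled), with a list adjusted p = 0.00975 (adjusted p = 0.688 with an estimated correlation) after scaling, and monocyte and macrophage markers 3 of 13 higher (adjusted p = 0.662, 2 and 0 scaled), with adjusted p = 0.0388 (adjusted p = 0.837 with an estimated correlation) over nuclear protein-coding genes. Excitatory neuron markers had 9 of 14 higher and 3 lower (adjusted p = 0.800, 4 and 5 scaled), where camera pointed lower and the median of 0.73 turned to -0.15 over nuclear protein-coding genes. Inhibitory neuron markers had 10 of 14 higher and 2 lower (adjusted p = 0.540, 3 and 3 scaled), and oligodendrocyte markers 9 of 14 higher (adjusted p = 0.752, 2 and 3 scaled). Astrocyte markers had 9 of 14 higher and 1 lower (adjusted p = 0.497, 5 and 3 scaled), oligodendrocyte precursors 7 of 12 higher and 1 lower (adjusted p = 0.761, 3 and 3 scaled) and endothelial markers 8 of 14 higher (adjusted p = 0.755, 3 and 1 scaled), and over nuclear protein-coding genes their medians turned to -0.06, -0.16 and -0.02. Pericyte and smooth muscle markers had 6 of 12 higher (adjusted p = 0.752, 1 and 1 scaled), and choroid plexus and ependyma 3 of 5 higher (adjusted p = 0.540, 3 and 0 scaled). Striatal markers had 8 of 14 higher and 1 lower (adjusted p = 0.755, 5 and 3 scaled), meningeal and fibroblast markers 8 of 14 higher (adjusted p = 0.752, 3 and 1 scaled) and erythroid markers 1 of 7 higher (adjusted p = 0.895, 1 and 0 scaled). Of the 3 lymphocyte markers 1 rose and 1 fell, and their median of 0.15 turned to -0.54 after scaling and ran from -0.07 to 0.52 with 1 library left out. Adjusted over the list alone, 2 monocyte, 5 pericyte and 11 inhibitory neuron markers rose, 1 oligodendrocyte marker fell, and the other counts were the same.

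Whether the knockdown moved the genes that differed between control oligo MCAO and sham was asked over those genes as a whole. The 8990 genes higher in MCAO had a median knockdown minus control oligo log2 change of 0.0640, and the 2178 lower genes one of 0.00709, with 0.0588 over all genes. The control oligo libraries enter both comparisons with opposite sign, so 1000 unchanged knockdown groups were simulated, which gave -0.0282 (SD 0.0800) and 0.0356 (SD 0.0906). Both medians lay inside the central 95% of the simulated values (-0.191 to 0.111 and -0.0955 to 0.255). The covariance of the 2 sets of log2 changes was 0.00762 against a simulated -0.0568 (central 95% of the simulated values -0.233 to 0.0260), a difference of 0.0644. The medians of the higher and lower genes were 0.0987 and 0.113 without control oligo replicate 2, 0.00220 and -0.0296 without replicate 3, 0.0316 and -0.00350 without knockdown replicate 2 and 0.0161 and 0.000974 with median-ratio scaling.

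The comparisons of control oligo and of knockdown with sham shared 8023 genes higher in both and 1896 lower in both, and 2 genes were called in opposite directions. Independent lists of these sizes would share 4741 and 273 genes. In 100 simulations of unchanged groups against the same sham libraries 22.1 and 25.8 genes were shared on average, with highest values of 1411 and 1399. After median-ratio scaling 3325 higher and 4230 lower genes were shared. Shared sham libraries gave fewer when simulated, so the excess may come from data set, oligo or MCAO.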

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

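TPM over nuclear protein-coding genes, the leukocyte covariate, fry and the estimated correlation beside other settings were chosen only after the results were seen, and the other alternatives were fixed before the data were examined. The cause was not tested where a result moved, unless the construction of the alternative gives it.

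Control oligo MCAO against sham had 11168 genes past the threshold. This count was 7191 with TPM over nuclear protein-coding genes, which takes structural and mitochondrial RNAs out of the total, and 5770 with an absolute log2 change of at least 1, which can only remove genes. It ran from 9492 to 11635 when 1 library was left out, and was 9439 with median-ratio scaling, 9716 with voom, 9416 with FPKM and 9693 with quantile normalization. Of the gene lists 19 passed, 1 with an estimated correlation, 35 with fry, which does not compare a list with other genes, and 17 to 21 with 1 library left out.

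Knockdown against control oligo had 2 genes past the threshold. It had 7 with no filter on low values, 4 with all 9 libraries in 1 fit, 4 with voom, 3 with median-ratio scaling, 2 with the leukocyte covariate and 0 with TPM over nuclear protein-coding genes, which leaves out both mt-Ts2 and Gm7808. It had 1 without any 1 of the control oligo libraries and up to 3 without knockdown replicate 2 or 4. Of the gene lists 9 passed, 0 with an estimated correlation, 0 with fry, and 10 (without control oligo replicate 2) to 25 (without knockdown replicate 2) with 1 library left out, where an estimated correlation left 0.

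Knockdown against sham had 11150 genes past the threshold, 6536 with TPM over nuclear protein-coding genes, 6233 with an absolute log2 change of at least 1, 9050 with voom, and 9266 to 12168 with 1 library left out. Of the gene lists 17 passed, 0 with an estimated correlation, 32 with fry, and 16 to 20 with 1 library left out.

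The replicate number as a block gave 11466 genes and 19 lists for control oligo against sham, 0 genes and 14 lists for knockdown against control oligo, and 11244 genes and 19 lists for knockdown against sham. Deviations from group means had no common sign of correlation at equal numbers, so these do not pair samples. The block drops degrees of freedom and libraries of unmatched number.

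The median knockdown effect over the genes lower in MCAO, 0.00709, ran from -0.0296 (without control oligo replicate 3) to 0.113 (without control oligo replicate 2), and that over the higher genes, 0.0640, from 0.00220 to 0.0987. With median-ratio scaling the comparisons with sham shared 3325 genes higher and 4230 lower in both, as scaling by construction takes the common shift out of both.

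Over all alternatives, the calls of the single genes under the naming rule, and of mt-Ts2 and Gm7808, that had passed were kept in 2696 cases and lost in 64 for control oligo against sham, kept in 28 and lost in 5 for knockdown against control oligo, and kept in 2656 and lost in 101 for knockdown against sham. In the same order, genes that had not passed gained a call in 6, 4 (all Nup62) and 14 cases and did not in 59, 2946 and 69.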

Other observations

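All tests in this part were chosen only after the results were seen.

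The classes of RNA differed between sham and MCAO libraries. TPM composition alone was excluded. Replication-dependent histones stayed lower in control oligo MCAO, at a median log2 change of -3.51 with TPM recomputed over nuclear protein-coding genes. A preparation that kept tail-less RNA in sham may explain a part of the falls. Small structural RNAs took 63.6% of sham TPM, and the MCAO kit selected poly(A) RNA. Outside the lists 252 small nuclear, nucleolar and Cajal body RNAs lay -1.79 from the all-gene median, 135 passing lower and 42 higher. Of them 67.1% were lower, under the 80% asked for, but RNAs of median 128 nt, under a 141 nt read, cannot decide it. As 0 data sets held both sham and MCAO, stroke and data set could not be separated.

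Knockdown replicate 4 was high in neutrophil, monocyte and cytokine genes, with Saa3, an acute-phase protein, at 8167 TPM against 0.931 to 364 in the other 5 MCAO libraries. Residual blood stays open, as its mean log2 over erythroid markers, -1.54 from theirs, lay in their range. A lower share of neural cells was excluded as the whole cause, because the smaller rise of the neutrophil and monocyte lists exceeded the largest rise of the oligodendrocyte, astrocyte and pericyte lists by 1.97, and the largest rise of the endothelial (1.18), meningeal (0.92) and pericyte lists by 1.49. A swap with a control oligo library remained possible, as 2 control oligo libraries (replicates 2 and 3) were nearer to knockdown replicates 2 and 3 than to the rest of their own group, and a stronger inflammatory response of this mouse was not tested. Against a swap, mt-Ts2 (0.814 TPM in this library, 125 to 141 in the control oligo libraries), Gm7808 (8.53 and 0) and Nup62 (28.2 and 3.01 to 6.10) followed the labels in all 6 libraries, but they were picked because they differ between the groups as labelled, so the swap stays open.

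The genes past the threshold between knockdown and control oligo were short features of uncertain value. Loss of the mitochondrial precursor RNA that spans mt-Ts2 was not decided by its neighbors mt-Th and mt-Tl2, as these are also shorter than a read. Their lower log2 change was -1.01, that of mt-Ts2 -6.27. mt-Th had 71.6, 74.2 and 229.6 TPM in knockdown replicates 2, 3 and 4 and 203 to 239 in control oligo. Without replicate 4 its change was -1.56 and that of mt-Tl2 -1.11, against -6.32 for mt-Ts2. A difference in the authors' processing between the groups could not be told from the effect of the oligo, as 67 transcripts lay far apart between the groups against at most 63 in the 9 other splits of the 6 libraries.

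Of the 10 splits of the 6 libraries of each comparison, 1 gave as many genes as the real one for control oligo against sham (highest other 1), 1 for knockdown against sham (highest other 0), and 4 for knockdown against control oligo (highest other 6), each count including the real split. Of the same splits 5, 10 and 10 passed as many gene lists as the real ones, which passed 19, 17 and 9 (highest other 26, 24 and 28). With 3 libraries against 3, 10 splits cannot give a share under 0.05. A split of the knockdown and control oligo libraries that passed 28 lists against 9 points to structure among the samples. The split with 6 genes set control oligo replicates 1 and 2 with knockdown replicate 4 against the rest, so differences between libraries within the groups were as large as the difference between the groups.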
